A study of Homo sapiens with 32 samples.

How the data were processed

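RNA was sequenced from 32 cell line clones: 16 WT and 12 AP1M1 KO-labelled clones of HEK293 and 2 WT and 2 KO-labelled clones of U2OS. Per the labels' protocols, frozen pellets were shipped to a service laboratory, total RNA was extracted with a column kit and libraries were made with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, reads were handled with bcl2fastq, FastQC, STAR and featureCounts on hg38, with no versions given. The deposited table of raw counts holds whole reads per gene for 44945 genes, per the submitters' processing notes, and the deposited TPM table holds the same genes scaled for length and depth. The strand setting of the counting is not stated, so values of overlapping and antisense genes are uncertain. Every column mapped to a label, and 0 columns were left out. Gene names came from the files, and positions from a RefSeq table for GRCh38, the build of hg38, in which 43282 of the genes were found, carrying at least 99.96% of the reads of each library.

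The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. CPM values were computed from the deposited counts with TMM factors in edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15) on the groups fitted. KO-labelled and WT clones of each line were compared with edgeR's two-sided quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. A fit over all 32 libraries tested whether the effect differed between lines, and a fit over the 16 HEK293 WT clones compared the suffixes SC2 and SC1. As all HEK293 KO-labelled clones carry SC1, their comparison was also run with the suffix as a term, on SC1 clones alone and against SC2 WT clones alone. Log2 fold changes are KO minus WT, or SC2 minus SC1, and those of edgeR have its default prior count. Log2 CPM values had a prior count of 2, apart from those of the permutation below. AP1M1 was also compared by permutation of log2 CPM (exact in U2OS and in SC1 clones, 100000 resamples in all HEK293 clones).

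Gene groups were tested with camera in limma 3.58.1 on log2 CPM, with an inter-gene correlation of 0.01 and at least 5 members. There were 35 lists of complexes, pathways and cell markers, of which 34 were tested: 0 of 26 mitochondrially encoded genes were found in the files. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. Beside the adjustment over all genes, each list's genes were also adjusted over the list alone. Named genes were AP1M1 and the AP-1 subunits. In addition, per line, 8 higher and 8 lower genes with the smallest p and 6 higher and 6 lower with the largest fold were taken among genes past the test at 1 CPM or more. A same sign in SC1 clones was required in HEK293, and groups without overlap in U2OS. The 6 genes with the smallest p for the difference between lines, up to 8 genes per direction called in both lines and the 4 members with the smallest p of each described list were added. Unnamed loci, antisense and small RNA genes were counted but not named. This rule named 1 gene in HEK293 and 0 in U2OS. After the values had been seen it was therefore also applied to the fits with the suffix as a term, on SC1 clones, against SC2 WT clones and, for U2OS, with all 32 libraries. Some of the genes it then named are left out of the text.

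Alternatives included RLE and upper-quartile factors, no filter, a 1 CPM minimum, DESeq2 1.42.0, limma on log2 TPM with pseudocounts of 1 and 0.1, a test against a fold of 1.5, robust dispersion and each clone left out in turn. Offsets for transcript length and GC content, fitted per library as smooth trends with mgcv 1.9.3, were added after the data were seen; 94.3% of tested HEK293 genes and 81.6% of tested U2OS genes had both values. Genes within 5 Mb of AP1M1 (2 and 10 Mb as alternatives) and whole chromosomes were examined for copy changes. The procedures were tested on simulated data with changes of 1.5-, 2- and 4-fold, drawn from the means and library sizes of the real samples. Of these changes, 85.1%, 98.5% and 98.5% were recovered for HEK293 among 15355 genes, 0%, 2.99% and 63.6% for U2OS among 20124, 11.9%, 34.3% and 83.3% for the difference between lines among 19117, and 68.7%, 94.0% and 100% for the WT suffixes among 15459. Calls of unchanged genes were 10 of 208, 10 of 54, 1 of 87 and 13 of 193 in that order. Many genes were changed at once, which makes the adjustment milder, so these rates hold for data with many changes. Computations used R 4.3.3, and figures Python 3.11.15 with matplotlib 3.10.9. Library totals ran from 22309480 to 37970874 counts.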

Results

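Messenger RNA levels were measured by RNA sequencing in 32 clones of a pair of human cell lines, HEK293 and U2OS, in which the gene AP1M1 had either been targeted with CRISPR-Cas9 or left intact. AP1M1 encodes the medium subunit of the AP-1 adaptor complex, which sorts membrane proteins into clathrin-coated vesicles at the trans-Golgi network and at endosomes. HEK293 is an embryonic kidney line, used here as a strongly adherent derivative that carries Cas9, and U2OS is an osteosarcoma line. Each library came from a separate clone per the labels. The HEK293 set held 16 wild-type (WT) clones and 12 clones labelled AP1M1 knockout (KO), and the U2OS set held 2 WT and 2 KO-labelled clones. The clone descriptions carry a suffix whose meaning the labels do not give: 6 HEK293 WT clones and the 12 KO-labelled clones have the suffix SC1, and 10 WT clones have SC2. The libraries held 22309480 to 33654513 counted reads in HEK293, with 19794 to 21251 genes detected. In U2OS they held 33850533 to 37970874, with 28557 to 30440 genes detected. Every pair of clones within a group differed by more than counting error: the chi-square statistic per degree of freedom ran from 4.18 to 138 over 188 pairs.

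AP1M1 (Entrez 8907, chromosome 19, positions 16197911 to 16245906 in hg38) was clearly lower than in WT clones in only part of the HEK293 clones labelled KO, and lower in both U2OS clones labelled KO. In HEK293 it stood at 93.5 ± 4.64 CPM, counts scaled to a common library size (SD, n = 16), in WT clones and at 82.7 ± 15.2 (SD, n = 12) in KO-labelled clones. Clones E6, E8, E2, E10 and E9 lay at 61.1, 61.7, 65.5, 69.0 and 72.1 CPM, below the WT range of 83.1 to 105, whereas the remaining 7 KO-labelled clones lay within it. In U2OS the WT clones had 55.6 and 54.5 CPM, clone A10 had 11.1 (20.2% of the WT mean) and clone B1 had 33.8 (61.5%). The transcript thus ran against the label in 7 of 12 HEK293 clones, and every direction below is that of the clones labelled KO. A nuclease edit can leave the transcript level of its gene unchanged, so the level alone does not show whether an edit is present. The log2 fold change was −0.18 (SE 0.0712) in HEK293, with an edgeR adjusted p of 0.585 over all genes and 0.0415 adjusted over the list alone, and −1.25 (SE 0.539) in U2OS, with an edgeR adjusted p of 0.398. A two-sided permutation test of log2 CPM gave p = 0.00826 in HEK293 and, in the SC1 clones alone, an exact p of 0.154. In U2OS the exact permutation p was 0.333, the smallest that 2 clones against 2 can give.

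**Figure D1:**
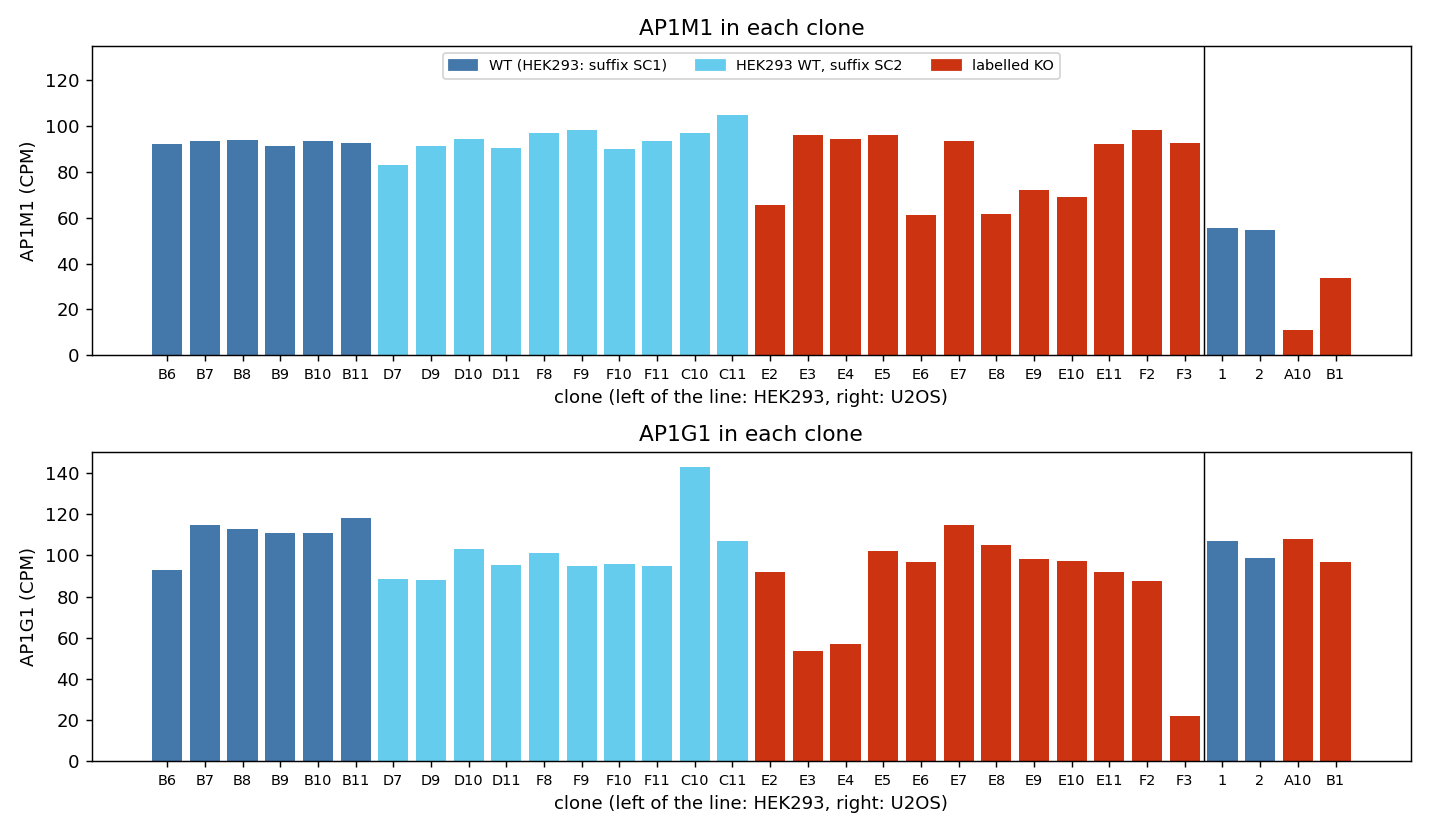
AP1M1 and AP1G1 in CPM (vertical axis) in each of the 32 clones (horizontal axis), by group. AP1M1 lay below the HEK293 WT range of 83.1 to 105 in 5 KO-labelled clones, and AP1G1 was lowest in clones F3 (22), E3 (53.6) and E4 (56.8).

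Among the other AP-1 subunits, AP1G1, AP1S3 and AP1B1 stood apart in HEK293. AP1G1 (Entrez 164, chromosome 16, positions 71729000 to 71808834), which encodes the large gamma subunit of the same complex, was at 104 ± 14 CPM (SD, n = 16) in WT clones. It was at 22 in clone F3, 53.6 in clone E3 and 56.8 in clone E4, or 21%, 51.3% and 54.4% of the WT mean. These 3 clones had AP1M1 within the WT range, at 92.8, 96.0 and 94.5 CPM. Over all KO-labelled clones the AP1G1 log2 fold change was −0.31 (SE 0.143), with p = 0.0806 by edgeR adjusted over the list alone. AP1S3, a small sigma subunit, went from 18.5 ± 2.31 to 15.5 ± 2.50 CPM, a log2 fold change of −0.26 (SE 0.0826), and AP1B1, the large beta subunit, from 259 ± 30.5 to 290 ± 20.3 CPM, 0.16 (SE 0.0568). Of the 8 AP-1 genes tested in HEK293, 1 was higher and 2 were lower adjusted over the list alone, and 0 passed over all genes. The list as a group had a median of −0.18 and did not pass camera, the competitive gene set test used throughout (adjusted p = 0.0695; adjusted p = 0.364 with an estimated correlation). In U2OS 0 of 8 passed adjusted over the list alone, with AP1M2, the epithelial form of the medium subunit, at a log2 fold change of 0.57 (SE 0.149). AP1G1 lay at 107 and 98.8 CPM in the WT clones and 108 and 96.9 in those labelled KO.

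In HEK293 clones labelled AP1M1 KO, genes for cholesterol synthesis rose slightly as a list against all WT clones, but not against those of the same suffix. SQLE, squalene epoxidase, an early oxygen-dependent enzyme of sterol synthesis (Entrez 6713, chromosome 8, positions 124998505 to 125022283), rose from 193 ± 35.9 CPM (SD, n = 16) in WT clones to 269 ± 32.3 (SD, n = 12), a fold of 1.39. It lay above the WT mean in 12 of 12 KO-labelled clones. HMGCS1, which makes the HMG-CoA used for sterols, was at 187 ± 32.5 and 239 ± 25.2 CPM, a fold of 1.27. Of the 24 tested genes of the cholesterol list, targets of the sterol-regulated factor SREBP2, 22 had a positive fold change and 12 were higher adjusted over the list alone. MVK, mevalonate kinase, was among them at a log2 fold change of 0.32 (SE 0.089). The list rose as a group with a median log2 fold change of 0.19 (camera adjusted p = 5.32e-15; adjusted p = 0.0847 with an estimated correlation). With the suffix as a term its median was 0.04 and did not pass (adjusted p = 0.244). Fatty acid synthesis genes rose as a group with a median of 0.09 (adjusted p = 0.0145; adjusted p = 0.706 with an estimated correlation). They did not pass with the suffix as a term (0.03, adjusted p = 0.388) or in SC1 clones alone (0.04, adjusted p = 0.366). Adjusted over the list alone, 3 of 14 were higher: SCD, a desaturase (0.21, SE 0.0635), FASN, the fatty acid synthase (0.35, SE 0.116), and FADS2, another desaturase (0.22, SE 0.0755).

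A pair of growth-related groups were slightly lower in the same clones against all WT clones, and neither held in every comparison with part of them. Of 100 splits of the 28 clones, the real one included, 82 gave at least the 4 lists that camera called here. Genes of the G2 and M phases of the cell cycle had a median of −0.08, with 39 of 44 below 0 and 0 past the test adjusted over the list alone (camera adjusted p = 6.48e-05; adjusted p = 0.719 with an estimated correlation). They did not pass with the suffix as a term (−0.04, adjusted p = 0.208) or in SC1 clones alone (−0.03, adjusted p = 0.207). The mitotic kinases TTK and BUB1 had log2 fold changes of −0.17 (SE 0.0525) and −0.14 (SE 0.0492). Cytosolic ribosomal protein genes had a median of −0.08, with 69 of 78 below 0 and 0 past the test adjusted over the list alone (camera adjusted p = 0.000262; adjusted p = 0.948 with an estimated correlation). Their median was −0.26 with the suffix as a term (adjusted p = 2.50e-10), 0.05 against SC2 WT clones (adjusted p = 0.487) and −0.03 without clones E3, E4 and F3 (adjusted p = 0.143). Among genes, 1 of 15444 passed by edgeR, SQLE, with a log2 fold change of 0.47 (SE 0.0829) and an adjusted p of 0.0423, while 1072 genes had an unadjusted p under 0.05. DESeq2 called 13 genes and limma on log2 TPM called 0. SQLE was not called when any of 19 of the 28 clones was left out one at a time or when clones E3, E4 and F3 were left out together. Its log2 fold change was 0.475 without those 3 clones. Over 19 settings other than the main one, that fit included and single clones left out not counted, it ran from 0.38 to 0.53. SQLE passed in 14 of them, with the lowest adjusted p, 0.000596, by DESeq2. It did not pass on log2 TPM, against a fold of 1.5 or without those 3 clones. Of simulated 1.5-fold changes, 85.1% were recovered at this size, in data with 208 calls. The adjustment is milder with that many calls, so the rate does not carry over to a result of 1 gene.

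**Figure D2:**
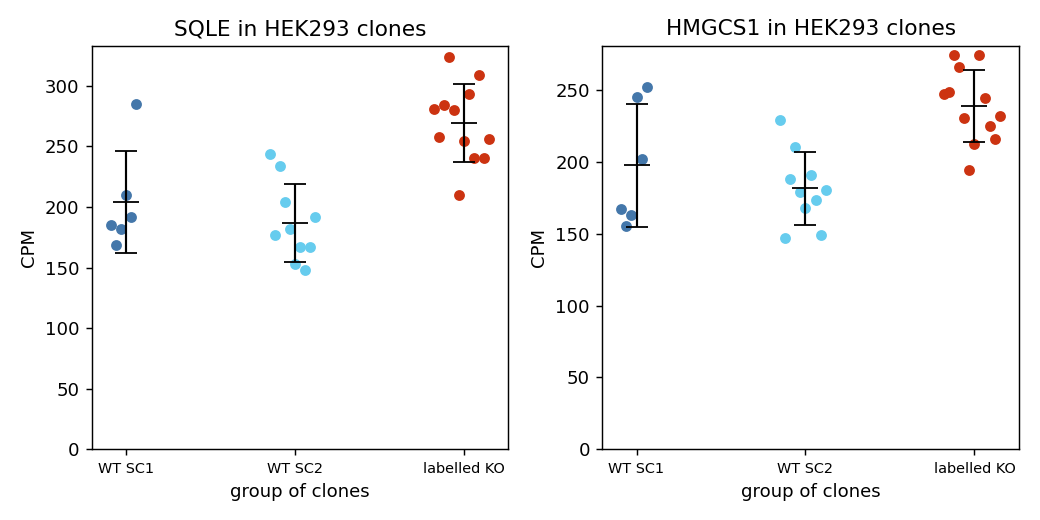
SQLE and HMGCS1 in CPM (vertical axis) in each HEK293 clone (points), with mean and SD per group: WT SC1, WT SC2 and labelled KO. All 12 KO-labelled clones lay above the WT mean of 193 for SQLE and of 187 for HMGCS1.

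Set against SC1 WT clones alone, which share their suffix, KO-labelled clones had higher genes for extracellular matrix and the amino acid stress response and lower genes for respiration, ribosomes and heat shock proteins. These are lists tested by camera at its preset correlation, which also called lists in most random splits of the HEK293 clones, as given below. Measures of GC content and transcript length were also higher on average, with no test. In the gene groups named, SC2 WT clones differed from the same 6 SC1 WT clones in the same directions. Against all WT clones the medians of KO-labelled clones were 0.047 for matrix and −0.0332 for the stress response. They were −0.0612 for respiration, −0.0794 for ribosomes and 0.0114 for heat shock. An effect of the label thus cannot be told apart from a shift of those 6 clones. The GC measure, the log2 deviation of genes high in GC minus that of genes low in it, was −0.13 ± 0.072 (SD, n = 6) in SC1 WT and 0.033 ± 0.0442 (SD, n = 12) in KO-labelled clones. The length measure, the deviation of long genes minus that of short ones, was −0.177 ± 0.203 (SD, n = 6) in SC1 WT and −0.00392 ± 0.173 (SD, n = 12) in KO-labelled clones. LTBP1, which stores latent TGF-beta in the matrix (Entrez 4052, chromosome 2, positions 32946953 to 33399509), was at 62.2 ± 6.23 CPM (SD, n = 12) against 41.5 ± 5.19 (SD, n = 6), a log2 fold change of 0.57 (SE 0.0806). LIN7C, a scaffold protein of cell junctions, fell by 0.66 on the log2 scale (SE 0.0757). Of 37 matrix genes, 16 were higher adjusted over the list alone, including the laminins LAMA1 (0.76, SE 0.136) and LAMB1 (0.55, SE 0.111) and the basement membrane collagens COL4A1 (0.44, SE 0.0915) and COL4A2 (0.49, SE 0.0924). The matrix list rose with a median of 0.34 (camera adjusted p = 9.68e-07; adjusted p = 0.535 with an estimated correlation), and with offsets for transcript length and GC content by 0.22 (adjusted p = 5.04e-06). Cargo receptors of the trans-Golgi network and endosomes rose with a median of 0.11 (adjusted p = 0.0114; adjusted p = 0.535 with an estimated correlation), but did not pass with the offsets (0.03, adjusted p = 0.222). Adjusted over the list alone, 6 of 25 were higher, among them the lipoprotein receptors LRP1 (0.85, SE 0.198) and LRP2 (0.51, SE 0.11) and the growth factor receptor EGFR (0.50, SE 0.112). Nuclear genes of oxidative phosphorylation fell with a median of −0.34, and 37 of 71 were lower adjusted over the list alone (adjusted p = 1.25e-14; adjusted p = 0.535 with an estimated correlation). With the offsets their median was −0.18 (adjusted p = 2.93e-11). Against SC2 WT clones the same list rose with a median of 0.12 (adjusted p = 1.53e-05; adjusted p = 0.725 with an estimated correlation). Integrated stress response genes rose with a median of 0.23 (adjusted p = 3.08e-05, and adjusted p = 0.587 with an estimated correlation), and with the offsets by 0.24 (adjusted p = 5.04e-06). In this list SC2 WT clones stood higher still over the same SC1 WT clones (0.515), so the rise was over SC1 WT clones only. Heat shock genes fell with a median of −0.22 (adjusted p = 6.37e-05; adjusted p = 0.535 with an estimated correlation), and had −0.19 with the offsets (adjusted p = 0.000367). Ribosomal protein genes fell with a median of −0.25 (adjusted p = 6.93e-09; adjusted p = 0.713 with an estimated correlation), and had −0.16 with the offsets (adjusted p = 1.68e-05). These 3 lists had the opposite direction in U2OS, and so had oxidative phosphorylation (0.428) and the matrix list (−0.216). The length measure also ran the other way there, but with the offsets each of these lists kept its direction in both lines. Against all HEK293 WT clones the stress response and heat shock medians had the same sign as in U2OS. Other genes called in this fit included FREM2, HDAC6, NFATC4, POU3F2, IGSF3 and OBSL1 among the higher, and VMA21, MAGT1, TMED7, CXADR, C21orf91, USP15 and SRPRB among the lower, with log2 fold changes of 0.40 to 0.89 and −0.52 to −0.38. The cholesterol list was smaller here, with a median of 0.05 that did not pass (adjusted p = 0.2), although SQLE (0.39, SE 0.102), SREBF2, which encodes SREBP2 itself (0.47, SE 0.0999), and LSS, lanosterol synthase (0.58, SE 0.132), were called.

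These SC1 values rest on 6 WT clones, and most of their gene calls did not hold with offsets for transcript length and GC content. edgeR called 1081 of 15689 genes, 444 higher and 637 lower, with 4208 under an unadjusted p of 0.05. With the offsets it called 247, of which 198 were among the 1081. With the suffix as a term in the model of all 28 clones it called 1756 of 16056. Against the 10 SC2 WT clones it called only 14 of 15471 genes, 8 higher and 6 lower, with 3095 under an unadjusted p of 0.05. SQLE (0.53, SE 0.0845), HMGCS1 (0.40, SE 0.072) and TCTA (0.42, SE 0.0749) were among the 8 higher, and MGAT5B, a glycosyltransferase (−0.70, SE 0.134), and ZBTB21, a zinc finger protein (−0.36, SE 0.0707), among the 6 lower. The cholesterol list rose with a median of 0.27 there, against 0.19 over all WT clones, and 18 of 24 genes were higher adjusted over the list alone (adjusted p = 3.71e-14; adjusted p = 0.148 with an estimated correlation).

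WT clones of HEK293 with the suffixes SC2 and SC1, alike in genotype per the labels, differed in 4681 genes. KO-labelled clones differed from all WT clones in 1 gene, but that fit pooled both suffixes. Its spread between WT clones thus included the difference between suffixes. With the suffix as a term the KO comparison called 1756 genes. The counts of 4681 and 1 therefore do not show which difference is larger. As lists tested by camera at its preset correlation, genes for respiration, ribosomes and heat shock proteins were lower in SC2 clones. Genes for extracellular matrix and the amino acid stress response were higher. The transcript length measure was higher on average as well, with no test, at 0.115 ± 0.0789 (SD, n = 10) in SC2 clones against −0.177 ± 0.203 (SD, n = 6) in SC1 clones, and so was the GC measure, at 0.0388 ± 0.102 against −0.13 ± 0.072. Oxidative phosphorylation genes fell with a median of −0.46 (camera adjusted p = 1.76e-18; adjusted p = 0.483 with an estimated correlation). Adjusted over the list alone, 63 of 71 were lower, such as the complex I subunits NDUFAB1 (−0.68, SE 0.0924) and NDUFA9 (−0.55, SE 0.074). Heat shock genes fell with a median of −0.44 (adjusted p = 1.39e-05; adjusted p = 0.66 with an estimated correlation), and 16 of 21 were lower adjusted over the list alone, HSPA8, a constitutive chaperone, at −0.66 (SE 0.146). Ribosomal protein genes fell with a median of −0.33 (adjusted p = 3.72e-08; adjusted p = 0.668 with an estimated correlation), and 44 of 78 were lower adjusted over the list alone, RPL34 at −0.75 (SE 0.145). Matrix genes rose with a median of 0.48 (adjusted p = 1.39e-05; adjusted p = 0.432 with an estimated correlation). Of 37, 18 were higher and 1 lower adjusted over the list alone, COL6A2, a collagen VI chain, at 1.02 (SE 0.127). Genes of the integrated stress response, driven by ATF4, rose with a median of 0.52 (adjusted p = 2.89e-06; adjusted p = 0.66 with an estimated correlation), and 17 of 36 were higher adjusted over the list alone, ALDH1L2, a mitochondrial folate enzyme, at 1.31 (SE 0.257). The cholesterol list fell with a median of −0.24 (adjusted p = 0.00895; adjusted p = 0.668 with an estimated correlation), with 13 of 24 genes lower and 2 higher adjusted over the list alone. With offsets for length and GC content the medians of these 6 lists were −0.23, −0.39, −0.13, 0.28, 0.53 and −0.17 in that order. Their camera adjusted p was then 2.78e-11, 9.94e-05, 0.0179, 0.000167, 6.07e-08 and 0.015. edgeR called 4681 of 15591 genes, 2331 higher and 2350 lower, and with offsets for length and GC content it called 3103, of which 2238 were among the 4681. limma on log2 TPM called 4537 higher and 860 lower. In a test against a fold of 1.5, 5 genes passed.

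**Figure D3:**
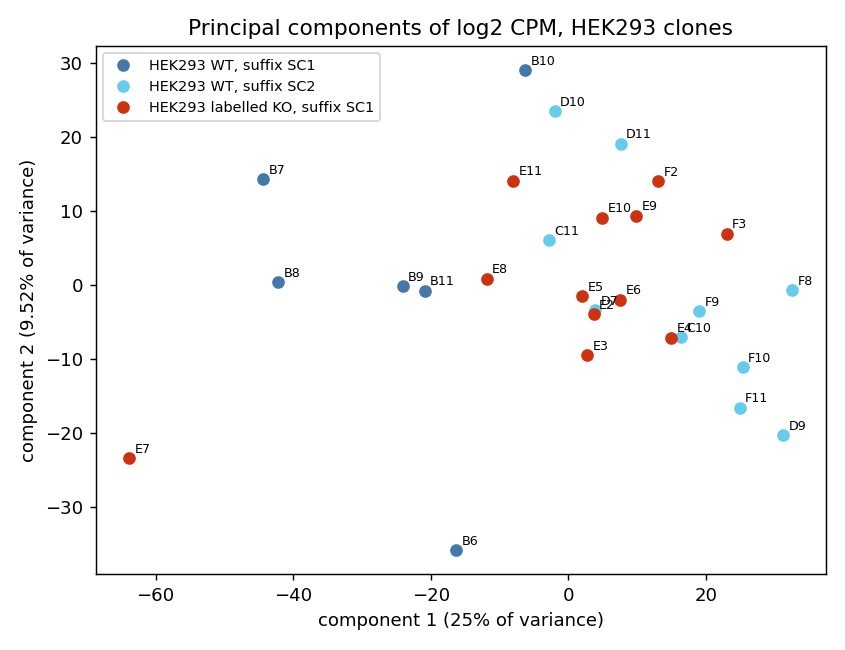
The 28 HEK293 clones on the first and second principal components of log2 CPM, which carry 25% and 9.52% of the variance, coloured by group and suffix. Each point is a clone, 6 WT SC1, 10 WT SC2 and 12 labelled KO.

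In U2OS clones labelled AP1M1 KO, genes of the amino acid stress response were lower and genes for ribosomal proteins and heat shock chaperones were higher, as lists tested by camera at its preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.491 each), and fry called 0 of 34 lists. By edgeR on the 4 libraries ASNS, FGF21, RPL24 and HSPA1A did not pass, with an adjusted p of 0.281 each. ASNS, asparagine synthetase, was at 21.3 and 30.6 CPM in the WT clones and at 4.78 and 4.83 in those labelled KO, a log2 fold change of −2.39 (SE 0.24), and FGF21, a stress-induced hormone, had −3.89 (SE 0.259). RPL24, a protein of the large ribosomal subunit, was at 116 and 115 CPM against 189 and 209, 0.83 (SE 0.11). HSPA1A, an inducible HSP70 that shares nearly all its sequence with HSPA1B, had 1.28 (SE 0.114), so the split of reads between both genes is uncertain. CDKN2B, the cell cycle inhibitor p15 (Entrez 1030, chromosome 9, positions 22002903 to 22009313), had 0 counts in both KO-labelled clones and 10.7 and 5.24 CPM in the WT clones. With a floor of 3 counts per library it was at least 94.6-fold lower than the WT mean and 62.2-fold lower than the lower WT clone; floors cover counting error only.

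The integrated stress response list fell with a median of −0.86 (camera adjusted p = 3.67e-15; adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone, 28 of 37 genes were lower, with PSAT1, of serine synthesis (−1.43, SE 0.182), and SLC6A9, a glycine transporter (−1.41, SE 0.176), among them. Ribosomal protein genes rose with a median of 0.55 (adjusted p = 8.23e-26; adjusted p = 0.491 with an estimated correlation), 78 of 78 above 0 and 58 higher adjusted over the list alone. Heat shock genes rose with a median of 0.61 (adjusted p = 3.13e-09; adjusted p = 0.491 with an estimated correlation), 20 of 20 above 0 and 10 higher adjusted over the list alone, AHSA1, a co-chaperone of HSP90, at 0.77 (SE 0.11). Oxidative phosphorylation genes rose with a median of 0.43 (adjusted p = 3.28e-16; adjusted p = 0.491 with an estimated correlation), 67 of 71 above 0 and 0 past the test adjusted over the list alone. With offsets for length and GC content these 4 medians were −0.86, 0.39, 0.54 and 0.29, and all passed camera. The length measure was 0.121 and 0.069 in the WT clones and −0.0652 and −0.138 in those labelled KO, and the GC measure −0.0651 and 0.0505 against −0.1 and 0.112.

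Smaller group changes were seen in the same U2OS clones, each with no call by an estimated correlation. Genes of S phase rose by 0.30 (adjusted p = 6.67e-06) and those of glycolysis by 0.32 (adjusted p = 0.000224), both with adjusted p = 0.491 with an estimated correlation. Cholesterol synthesis genes rose by 0.35 (adjusted p = 0.000168; adjusted p = 0.564 with an estimated correlation), but did not pass without clone A10 (0.17, adjusted p = 0.0802). In these 3 lists 0 members passed the test adjusted over the list alone. Genes of G2 and M phase rose by 0.26 (adjusted p = 3.05e-05; adjusted p = 0.564 with an estimated correlation), but without A10 the list did not pass (0.09, adjusted p = 0.101). They included BIRC5, CCNB1 and CKS2, regulators of mitosis, at 0.65, 0.71 and 0.71. Matrix genes fell with a median of −0.22 (adjusted p = 0.00961; adjusted p = 0.573 with an estimated correlation), 31 of 45 below 0 and 0 past the test adjusted over the list alone. ITGB3, an integrin, was at −1.70 (SE 0.234) and TAGLN, an actin-binding protein, at −1.51 (SE 0.259). The matrix list rested on clone A10: its median was −0.02 without A10 (adjusted p = 0.902) and −0.54 without B1, and it did not pass over all 32 libraries (−0.28, adjusted p = 0.0525). Of 34 lists camera called 15, 13 higher and 2 lower, and 0 of the 15 held with an estimated correlation.

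By edgeR on the 4 libraries alone 0 of 20621 U2OS genes passed, with the smallest adjusted p at 0.281 and 2893 genes under an unadjusted p of 0.05, while DESeq2 called 431 and limma on log2 TPM 0. With the spread taken from all 32 libraries 142 genes passed, 38 higher and 104 lower. That spread came mostly from HEK293 clones, so the adjusted p values of this fit do not measure the spread of U2OS clones. Among the lower were CD248, the stromal receptor endosialin (−6.23, SE 0.559, adjusted p = 9.97e-09), EMILIN1, a glycoprotein of elastic fibres (25.7 and 19.8 CPM in WT clones, 2.76 and 2.87 in those labelled KO; −3.02, SE 0.345, adjusted p = 2.85e-06). They also held the matrix genes BGN and ELN (−3.27 and −3.25) and CDK14, a cyclin-dependent kinase (−1.07). Among the higher were TGM2, a transglutaminase that crosslinks proteins (89.4 and 86.8 CPM against 256 and 196; 1.36, SE 0.268, adjusted p = 0.00784), and the growth factor BMP4 (0.86, SE 0.173). FGF5 (1.14), FAM126A (0.88), SUMO3 (0.90) and RAB38 (1.11) were higher as well. On the 4 libraries, BMP4 stood at 0.59 without A10 and CDK14 at −0.68 without B1. NLRP2, PHYHD1, ADD2 and ALX4 were also lower, and PTTG1IP, OSBPL3, DCLK1 and TBXAS1 also higher, by −5.78 to −2.17 and 0.71 to 1.54 on the log2 scale. The clones labelled KO differed from each other more than the WT clones did. Over 12267 genes the median absolute log2 difference was 0.284 between A10 and B1 and 0.0724 between the WT clones. By chi-square per degree of freedom the WT pair was the closest of all 188 pairs (4.18, against 86.7 for A10 and B1). Whether the WT pair are independent clones, as labelled, was not tested, so their spread may be too small a measure of that between clones. Without clone A10 edgeR called 9990 genes and without clone B1 7900, each resting on a single KO-labelled clone assumed to vary like the WT pair. Of simulated changes in this design 63.6% were recovered at 4-fold and 2.99% at 2-fold, and 10 of 54 calls were of unchanged genes.

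**Figure D4:**
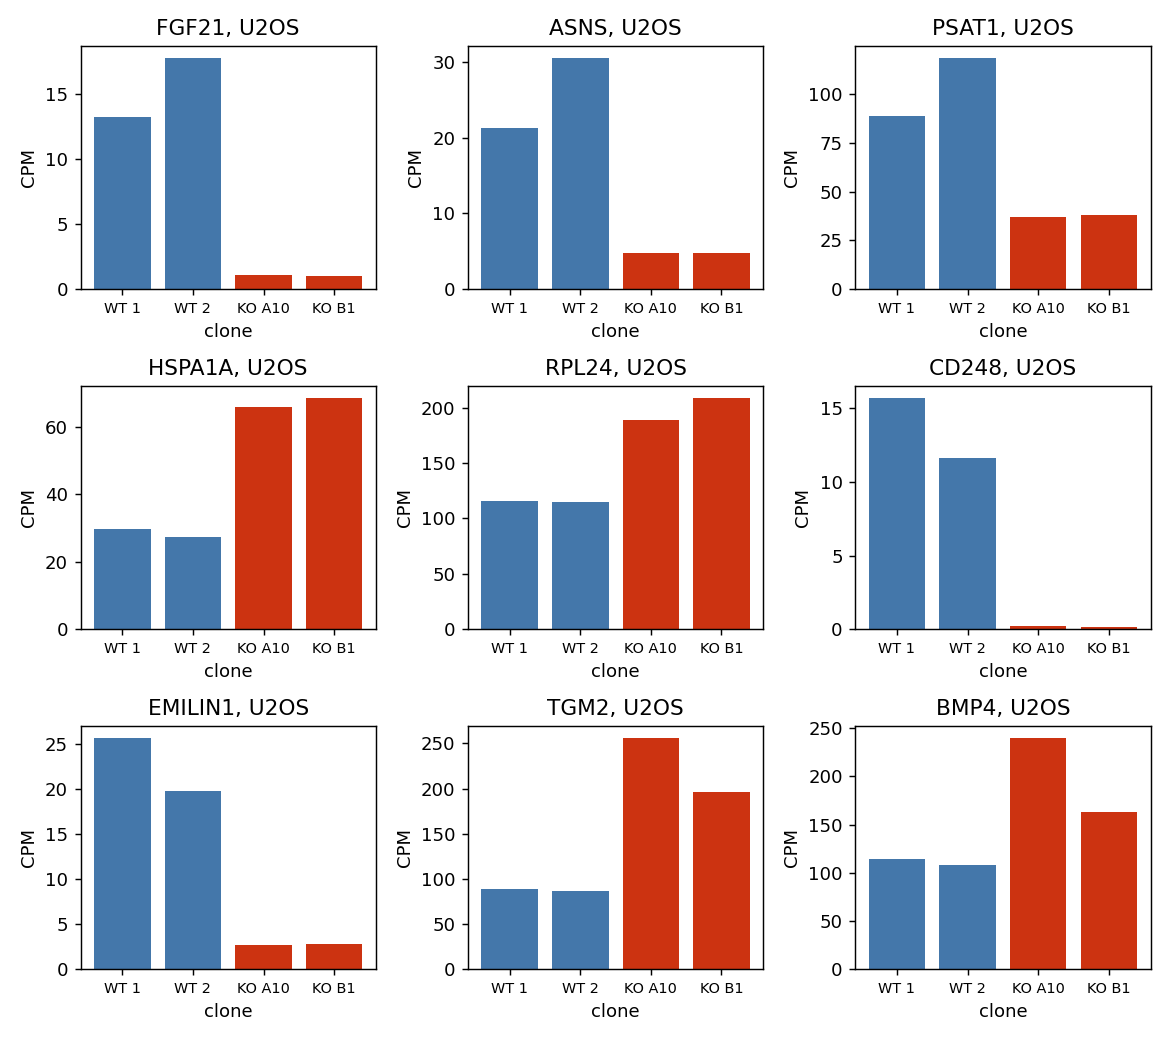
CPM (vertical axis) of 9 genes in the 4 U2OS clones (bars, 1 per clone). ASNS and EMILIN1 stood at 4.78 and 4.83 and at 2.76 and 2.87 in the KO-labelled clones, and TGM2 at 256 and 196 against 89.4 and 86.8 in WT clones.

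The effect of the KO label differed between the lines in the stress response, ribosomal and heat shock genes, and in a small set of genes led by CDKN2B. Fold changes in U2OS minus those in HEK293 had a median of −0.85 for the integrated stress response, 0.58 for ribosomal proteins and 0.50 for heat shock (camera adjusted p = 1.49e-05, 2.91e-14 and 0.000785; adjusted p = 0.58 each with an estimated correlation). EMILIN1 had a difference of −3.15 (SE 0.366), SLC1A5, a glutamine transporter, −1.10 (SE 0.171), and SRPK2, a kinase of splicing factors, −0.74 (SE 0.115). By edgeR on all 32 libraries 71 of 21622 genes differed, 18 higher and 53 lower in U2OS, with 1924 under an unadjusted p of 0.05. The spread in this fit came mostly from HEK293 clones, so these calls too do not measure the spread of U2OS clones. By camera 8 of 34 lists differed, while 0 held with an estimated correlation (smallest adjusted p = 0.387). The count was 16 and 10 without U2OS WT clones 1 and 2, and 652 and 193 without the KO-labelled clones A10 and B1. Cholesterol synthesis genes had a median difference of 0.08 that did not pass (adjusted p = 0.555).

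Few genes changed the same way in both lines. GTPBP10, a mitochondrial ribosome factor, and ARMCX5 were lower in both, with log2 fold changes of −0.22 and −0.31 in HEK293, with the suffix as a term, and −0.65 and −1.09 in U2OS, with the spread of all 32 libraries. In U2OS they were at 28.4 ± 0.375 and 7.75 ± 0.127 CPM in WT clones and at 18.1 ± 5.66 and 3.66 ± 2.06 in KO-labelled clones (SD, n = 2 each). They were the only genes called in both of these fits with the same sign, against 5.32 lower and 1.56 higher that independent lists would share, and 3 genes were called with opposite signs. The Spearman correlation of fold changes across 14452 genes was 0.00311, and −0.288 when HEK293 SC1 clones alone were used; genes are not independent replicates. Genes within 5 Mb of AP1M1 on chromosome 19, a measure of copy loss around the targeted site, had a median log2 fold change of −0.000334 over 184 genes in HEK293 (camera p = 0.906) and 0.0533 over 229 genes in U2OS (p = 0.405). Of 23 chromosomes 0 differed between HEK293 KO-labelled and WT clones by a permutation test of their median expression. Spread between clones was alike in size across groups, with a median SD of log2 CPM over 15444 genes of 0.224 in KO-labelled, 0.253 in SC1 WT and 0.213 in SC2 WT clones.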

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

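Chosen after the result was seen were the length and GC offsets and the tests of GC content and length as the whole cause, of the same in SC1 clones, of a batch shared by SC1 libraries, of the suffix in the cholesterol genes and, for AP1G1, of a low AP1M1. So were the splits that keep the suffix, although their bounds were set before they were run. The effect of the KO label differed between U2OS and HEK293, by a test of the difference itself, in 71 genes. That test took its spread mostly from HEK293 clones, so it does not measure the spread of U2OS clones, with 2 per genotype. CDKN2B had the largest negative difference of those named, with a fitted log2 value of −10.90 that depends on the prior count because both KO-labelled U2OS clones had 0 counts. EMILIN1 differed by −3.15, PHYHD1 by −2.37, ADD2 by −2.11, SRPK2 by −0.74 and SLC1A5 by −1.10. Among gene lists the median differences were −0.85 for the integrated stress response, 0.26 for S phase, 0.28 for G2 and M phase, 0.27 for glycolysis and hypoxia, 0.46 for oxidative phosphorylation, 0.58 for ribosomal proteins, 0.50 for heat shock and −0.26 for extracellular matrix. These 8 lists passed camera at its preset correlation and 0 passed with an estimated correlation, where the smallest adjusted p was 0.387.

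HEK293 WT clones with the suffixes SC2 and SC1 differed in 4681 genes, and 1 of 100 splits of the 16 clones, the real one, reached that count, so chance can be excluded (highest other 1166, with 5 of the 6 SC1 clones in 1 group). Against a difference in depth or a few dominant genes, 4609 genes were called after all libraries were thinned to the lowest total and 4623 without the 100 most abundant genes. Against a batch shared by all SC1 libraries, KO-labelled clones, also SC1, differed from SC2 WT clones in 14 genes and from SC1 WT clones in 1081. As the whole cause, length and GC content are argued against by the 2190 genes kept with the same sign, but only as far as the offsets capture them. Smooth trends on 1 transcript per gene can leave bias behind, so they are not excluded. As part of the cause they stay open: offsets left 3103 genes, 66.3% of the count without (3033 with principal transcripts). This was just under the bound of 67 percent set in advance as arguing against them. A real difference between the origins of the clones was not tested, and for the 1081 SC1 genes, where the real split alone of 100 reached that count (highest other 368), length and GC content remain a candidate explanation of most calls, as 247 were left.

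AP1G1 was low in the HEK293 KO-labelled clones E3, E4 and F3, which had AP1M1 within the WT range. Loss of chromosome 16 copies is argued against by genes within 5 Mb of AP1G1, whose lowest median log2 deviation in the 3 clones was −0.05 (−0.0509). A fall of AP1G1 secondary to a low AP1M1 transcript is argued against as well, since 0 of the 5 clones with AP1M1 below the WT range had AP1G1 below it. An edit at AP1G1 was not tested, because the sequence at either gene was not available.

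Cholesterol synthesis genes were higher in HEK293 clones labelled KO, with a median of 0.186, and 1 of 100 splits of the clones, the real one, gave a median as far from 0 (highest other 0.167). Among splits that take the 12 clones from the SC1 clones, as the labels do, 37 of 100 gave one (median of the others 0.174, highest other 0.239). Chance can thus not be excluded for this median. Splits that ignore the suffix can place SC2 clones in the group of 12, which the labels do not. Each split also scored this list alone, not the most extreme of all lists tested. GC content and length are argued against, as the median was 0.165 with offsets, 88.4% of the value without. The SC1 clones alone gave a median of 0.0459 in the same direction with a fry p of 0.133, and SC2 WT clones lay at −0.237 from SC1 WT clones. Most of the 0.186 was thus not seen between clones of the same suffix. Whether a small effect of the label remains cannot be told, as the test within SC1 clones did not pass. For the number of lists past the test, 4, chance cannot be excluded: 82 of 100 splits gave as many, up to 14. With the suffix kept, 98 of 100 did, with a median of 9 among the others. Camera at its preset correlation thus called lists under random splits of these clones. List calls of the other comparisons were not set against splits, so their camera p values do not exclude chance.

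For single genes in HEK293, 3 of 100 splits of the 28 clones, the real one included, gave at least the 1 gene called against all WT clones. The highest other split called 1290 genes, with 4 of the 6 SC1 WT clones in its group of 12. Whether the place of those clones accounts for the calls was not tested. Of 100 splits that take the 12 clones from the SC1 clones, 19 gave as many (highest other 4210), so chance cannot be excluded for this count once the suffix is kept. These splits count any gene and do not test SQLE itself. By edgeR SQLE passed with the suffix as a term (adjusted p = 0.0233) and in SC1 clones alone (adjusted p = 0.0297). Against SC2 WT clones 1 of 100 splits, the real one, gave 14 genes (highest other 1), so chance can be excluded there, but those groups differ in suffix too.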

How the results depend on the processing

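The length and GC offsets, the fits without clones E3, E4 and F3 and the list tests against SC2 WT clones, with offsets and over all 32 libraries were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers. For HEK293 KO against WT, where edgeR called 1 gene, DESeq2 called 13, limma on log2 TPM 0 in each of its 3 forms, and the test against a fold of 1.5 0. The model with the suffix called 1756, SC1 clones alone 1081, SC2 WT clones 14 and offsets 2. SC1 clones with offsets gave 247 (283 with principal transcripts), the fit without E3, E4 and F3 0, and leaving out 1 clone 0 to 4 (2 without E7 or D10, 3 without C11, 4 without D11). For U2OS, where edgeR called 0, no filter gave 1, DESeq2 431, all 32 libraries 142 and leaving out 1 clone 0 to 9990. The 71 genes that differed between lines became 39 with no filter, 241 by DESeq2, 3462, 2349 and 478 by limma on log2 TPM with pseudocounts 1 and 0.1 and with a minimum of 1 TPM. They became 10 against a fold of 1.5, 337 without SC2 WT clones and 10 to 652 without 1 U2OS clone. The 4681 genes between WT suffixes became 5 against a fold of 1.5, 3103 and 3033 with offsets and 3398 to 5671 without 1 clone (without B7 and B10). By limma on log2 TPM they split 4537 higher to 860 lower, against 2331 to 2350 by edgeR. AP1M1 in U2OS had a log2 fold change of −1.30 with all 32 libraries, past the threshold, and of −0.665 without A10 to −2.26 without B1, also past it. Of 34 lists, 4 passed in HEK293, against 0 with an estimated correlation, 2 with fry (1 of the 4), 6 with the suffix (1 of the 4), 11 against SC2 WT clones (3 of the 4) and 9 with offsets (all 4). In U2OS 15 passed, against 0 with an estimated correlation, 0 with fry, 8 over all 32 libraries (all among the 15) and 10 to 16 without 1 clone. The correlation between lines of 0.00311 was −0.288 with SC1 clones and −0.0476 to 0.0315 without 1 U2OS clone, and the KO spread of 0.224 was 0.181 at 5 CPM or more. Medians that reversed in HEK293 were the integrated stress response (0.217 with the suffix, 0.226 in SC1 clones), heat shock (−0.232 and −0.223), oxidative phosphorylation (0.12) and ribosomal proteins (0.0532), both against SC2 WT clones. In U2OS p53 targets reversed to −0.262 without A10 (0.65 without B1), and interferon-stimulated genes to −0.0285 without B1 (0.62 without A10). On log2 TPM, U2OS medians reversed for lysosomal (−0.0911), fatty acid (−0.0139), unfolded protein response (−0.0514), p53 (−0.0204) and RNase H genes (−0.0159). Apart from fits on fewer clones, the cause was not tested. Of list values in HEK293 and U2OS, 239 and 275 kept sign and side of the threshold, 24 and 10 gained a call, 14 and 48 lost it and 6 and 7 reversed in a called value. A further 57 and 34 changed sign with no call in either fit. Of named gene values, 798 and 587 kept both, 114 and 148 gained a call, 5 and 0 lost it and 0 and 0 reversed in a called value, while 25 and 15 changed sign with no call in either fit. AP1M1 in HEK293 ran from −0.418 to −0.145 over 47 settings and passed over all genes in 0. With 2 clones per group in U2OS, 63.6% of simulated 4-fold and 2.99% of 2-fold changes were recovered.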

Other observations

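The tests with offsets and the measures of transcript length were chosen after the results were seen. Several further gene groups changed in U2OS clones labelled KO, and each of these calls was lost without 1 of the 4 clones and over all 32 libraries. Interferon-stimulated genes rose with a median of 0.37 (30 of 36 above 0; camera adjusted p = 0.0138, adjusted p = 0.654 with an estimated correlation), and p53 targets with 0.27 (25 of 30; 0.0434, and adjusted p = 0.79 with an estimated correlation). Interferon genes had −0.03 without clone B1 and 0.62 without A10, and p53 targets −0.26 without A10 and 0.65 without B1. Unfolded protein response genes rose with 0.17 (22 of 25; 0.00961, and adjusted p = 0.539 with an estimated correlation) and fatty acid synthesis genes with 0.22 (10 of 14; 0.0247, and adjusted p = 0.539 with an estimated correlation). Lysosomal genes rose with 0.16 (42 of 63; 0.047, and adjusted p = 0.491 with an estimated correlation) and genes for RNase H and oligonucleotide handling with 0.22 (18 of 20; 0.00961, and adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone, 3 fatty acid genes were higher, ELOVL6, an elongase (0.64, SE 0.121), TMEM97, a sterol-regulated membrane protein (0.60, SE 0.122), and FASN (0.59, SE 0.122), and 0 genes of the other 5 lists were. Without B1 the fatty acid (0.08, adjusted p = 0.332), lysosomal (0.03, adjusted p = 0.387) and unfolded protein response lists (0.15, adjusted p = 0.0505) did not pass. The fatty acid list did not without WT clone 2 either (0.18, adjusted p = 0.0846), nor the lysosomal list without WT clone 1 (0.18, adjusted p = 0.0619) or the RNase H list without A10 (0.14, adjusted p = 0.294). Over all 32 libraries the adjusted p was 0.0525 for interferon genes, 0.0588 for p53 targets, 0.0561 for the unfolded protein response, 0.109 for fatty acid synthesis and 0.087 for the lysosomal and RNase H lists. With offsets for length and GC content the lysosomal list did not pass either (median 0.118, adjusted p = 0.0629).

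In HEK293 WT clones the SC2 group also had lower replication-dependent histone genes (median −0.52; camera adjusted p = 0.00221, adjusted p = 0.461 with an estimated correlation). Adjusted over the list alone, 9 of 27 were lower and 1 higher, with the linker histone H1-2 at −1.10 (SE 0.253). Unfolded protein response genes had a median of −0.19 (11 of 25 lower adjusted over the list alone; 0.0109, and adjusted p = 0.461 with an estimated correlation), with CALR, the chaperone calreticulin, at −0.51 (SE 0.11). Epithelial adhesion genes had 0.36 (9 of 21 higher and 1 lower adjusted over the list alone; 0.0364, and adjusted p = 0.461 with an estimated correlation), with DSP, desmoplakin, at 0.68 (SE 0.144). Genes for RNase H and oligonucleotide handling had −0.19 (10 of 19 lower and 1 higher adjusted over the list alone; 0.0108, and adjusted p = 0.461 with an estimated correlation). The receptors LRP1 (1.35, SE 0.161) and EGFR (0.80, SE 0.11) were higher in SC2 clones. With the offsets the histone, adhesion and RNase H lists no longer passed, with medians of −0.283 (adjusted p = 0.243), 0.239 (adjusted p = 0.0565) and −0.0778 (adjusted p = 0.078).

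Whole chromosomes stood apart in some clones, as values with no test. Genes on chromosome 21 had a median log2 deviation of −0.514 in the HEK293 KO-labelled clone E7, and those on chromosome 4 had −0.451, −0.41 and −0.381 in the WT clones F8, F9 and C10. In the U2OS clone B1 genes on chromosomes 14, 18 and 20 had −0.406, −0.406 and −0.40, and in clone A10 those on chromosome 22 had −0.31. AP1G1 was highest in the HEK293 WT clone C10, at 143 CPM, where genes within 5 Mb of it had a median deviation of 0.472. By the measure of transcript length, long genes minus short ones, clone E7 was the lowest of all HEK293 clones, at −0.501, below the SC1 WT clone B6 (−0.336). On the first principal component it lay at −63.88, near the SC1 WT clones B7 (−44.36) and B8 (−42.21). The other KO-labelled clones lay from −11.89 to 23.02. Chromosomes 3 and 5 had −0.306 and 0.189 in E7, −0.333 and 0.28 in B7, and −0.293 and 0.233 in B8. Chromosome 3 was also low in the SC2 WT clone C11 (−0.283). On chromosome 8 the clones differed, with −0.215 in E7 against 0.0987 in B7 and 0.0822 in B8.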
